A study of Homo sapiens with 18 samples.

How the data were processed

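RNA was precipitated and sequenced from 2 stable H1299 lines that express Flag-tagged YTHDF2, wild type or K571R, after silencing of the endogenous gene. Per the labels' protocols, m6A precipitation used an antibody to m6A, RNA immunoprecipitation an antibody to Flag, and rRNA was removed before RIP and RNA-seq libraries were made. Reads were 150 bp paired-end, from a HiSeq instrument for MeRIP and RIP and a NovaSeq for RNA-seq, per the labels' protocols. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cuffdiff 2.2.1 and Cufflinks and the build hg19, without saying which step each served. The peak caller's version and settings are not given in the sources used here.

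The RIP tables, 1 per Flag precipitate with its input and, in the first experiment, its IgG precipitate, and the RNA-seq tables, 1 per library, held FPKM values that the authors deposited per protein-coding gene, normalized to gene length and library size, per the file headers. The same tables held an estimated count per gene, deposited by the authors, not whole, and whether Cuffdiff had scaled it between libraries is not given in the sources used here. For the 2 IgG precipitates the deposited columns are headed FPKM and count but were treated as a signal of unknown scale: all of their nonzero values had at most 6 significant digits after division by 0.45, against 19.5% to 21.5% as they stood, whereas the other columns had such values in over 99.9% as they stood. The factor was found from the values alone, and it scales the deposited IgG levels down by a constant. Its use raises every ratio of Flag to IgG. The peak lists gave, per the file headers, a fold enrichment for each peak, which is a ratio of precipitate to input made by the authors. They also gave the authors' score for each peak and a false discovery rate, both as deposited by the authors; that the rate is in percent was read from its values. Each list came from 1 line, and levels per gene in the MeRIP libraries were not analysed here.

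Samples were grouped by the titles in the labels. The inputs titled for ginkgolic acid and 2-D08 carry an untreated entry in another label and were grouped by title, so that those cells had been treated rests on the title. Tables were joined by gene identifier, and the 20307 identifiers were summed to 20232 symbols, 74 of which had more than 1 identifier. The tables merge overlapping genes into shared loci, so coordinates are those of loci, and values of overlapping genes, read-through genes and near-identical copies such as SMN1, HSPA1A and the histones are uncertain. Gene names in the peak lists matched the tables for 98.2% of WT peaks and 98.1% of K571R peaks.

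All differences are on the scale log2(FPKM + 1), which understates the change of low genes, among genes with a mean of at least 1 FPKM over the libraries compared. Comparisons of conditions set levels across tables, which may have been normalized separately. Enrichment was log2 of Flag precipitate over input, and contrasts of binding were differences of enrichment. The threshold was 2-fold. With 1 library per group, nothing measures the spread between cultures. Counting standard errors were computed from the estimated counts, and each contrast was set beside simulated libraries with Poisson counts and no effect. Reads without molecular identifiers are not independent molecules, so these errors are a lower limit. The simulated libraries may hold more than counting noise, since their calls under ginkgolic acid were uneven, at 1054 higher and 456 lower. Genes called bound, enriched at least 2-fold, were, for the main binding contrasts, taken from the other experiment's untreated pair than the one in which the effect was measured, since choosing them in the same pair biases the effect: chosen in their own pair, medians were −0.39 for K571R, −0.05 for ginkgolic acid and −0.26 for 2-D08. Medians of gene sets and lists were given as percentiles among 10000 random sets of the same size drawn from 50 bins of mean expression, and again from 100 bins of expression and effective length (the ratio of count to FPKM, at 10 counts or more). Peaks were shared at an overlap of 1 base or more.

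The lists, fixed before the data were examined, were 28 lists of symbols and 4 families by symbol pattern. They covered m6A, RNA decay and SUMO factors, reported YTHDF2 targets, stress, growth, metabolic and signalling pathways, neuroendocrine markers and markers of other cell types. Genes named in the text followed a rule also fixed before the data were examined. It took YTHDF2 in every library. For each contrast it took the 10 highest and 10 lowest genes with a mean input or RNA-seq level of at least 5 FPKM that differed by at least 0.58 on the log2 scale in the same direction in a second comparison, which was the other untreated pair for RIP and the RIP inputs for RNA-seq. Of each list described it took up to 4 members with the largest differences, then every measured reported YTHDF2 target, the 5 shared and 5 unshared peaks of highest fold, and peaks in reported targets. The plan had assumed FPKM per transcript. The tables were per gene, so a planned comparison with the most abundant transcript was not run.

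The steps were tested on simulated data in which 100 genes per fold size were changed and Poisson counting noise was added. Each simulated count was turned into FPKM by its own library's ratio of count to FPKM for that gene. Differences between libraries in that ratio thus entered too, and calls of unchanged genes are not from counting noise alone. Of genes changed 2-fold and 4-fold, the threshold recovered 41% and 90% for K571R minus WT enrichment (11994 genes), 35% and 81% for ginkgolic acid (11674 genes), 40% and 85% for 2-D08 (11782 genes), 40% and 94% for RNA-seq (12017 genes), 33% and 92% for the K571R and WT inputs (12103 genes), 36% and 94% for the ginkgolic acid inputs (11292 genes) and 30% and 93% for the 2-D08 inputs (11412 genes). It called 5.23%, 13.3%, 10.6%, 1.06%, 3.09%, 1.33% and 1.03% of unchanged genes in the same order. Of 1000 lists of 20 genes drawn at random from the measured RNA-seq differences, 4.5% fell outside the middle 95%, as such drawing gives by construction. Of 200 of these lists shifted by 0.3 on the log2 scale, 94.5% lay above the middle 95%.

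Alternatives were a pseudocount of 0.1, no filter or a minimum of 5 FPKM, centring on all tested genes, another untreated WT pair, bound genes at a log2 enrichment of at least 2, IgG as the reference, sets matched on effective length, the RIP inputs in place of RNA-seq, stricter peaks and a 50% overlap. Estimated counts scaled to library size (CPM) in place of FPKM, IgG divided by its factor and 3 alternatives for the lists were added after the data had been seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.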

Results

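RNA bound by YTHDF2, m6A marks and mRNA levels were measured in H1299 cells, a human non-small cell lung carcinoma line. YTHDF2 is a cytoplasmic protein that reads N6-methyladenosine (m6A) in mRNA and recruits deadenylation and decay factors. Endogenous YTHDF2 had been silenced by a short hairpin RNA, and Flag-tagged YTHDF2 was put back in 2 stable lines, either wild type (WT) or K571R, in which a lysine reported to accept SUMO is an arginine. The 18 samples were 4 libraries of m6A immunoprecipitation with inputs (MeRIP), 12 libraries of RNA immunoprecipitation (RIP) and 2 RNA-seq libraries. Each group held 1 library, so no spread between replicates could be measured, no p-value across replicates was possible, and errors on single genes cover counting only. The RIP libraries formed 5 pairs of a Flag precipitate and its input. A first experiment compared WT with K571R and also had IgG precipitates, and a second compared untreated WT cells (control) with WT cells given ginkgolic acid for 12 h or 2-D08 for 24 h. Ginkgolic acid blocks the SUMO-activating enzyme and 2-D08 the transfer of SUMO from its conjugating enzyme. Estimated counts on protein-coding genes summed to 8319772 and 8519392 for the WT Flag precipitate and input, 8428036 and 8537427 for K571R, 7089698 and 5436513 for the control, 6724101 and 4846888 under ginkgolic acid, and 6721612 and 5288892 under 2-D08. The RNA-seq libraries held 7415336 for WT and 7418490 for K571R.

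YTHDF2 mRNA itself, which in these lines sums what remained of the endogenous transcript and the transgene, was higher in K571R than in WT cells. It stood at 196 FPKM in WT and 292 FPKM in K571R RNA-seq, a log2 difference of 0.57 (counting SE 0.04), and at 144 and 229 FPKM in the RIP inputs. In the second experiment the inputs held 88.0 FPKM of YTHDF2 in control cells, 58.0 under ginkgolic acid and 31.7 under 2-D08. The Flag precipitates held 107 FPKM of YTHDF2 mRNA in WT, 215 in K571R, 873 in control, 576 under ginkgolic acid and 409 under 2-D08. Relative to input, YTHDF2 mRNA was thus depleted or level in the first experiment (log2 −0.42 in WT and −0.09 in K571R) and enriched in the second (log2 3.30 in control, 3.29 under ginkgolic acid and 3.65 under 2-D08). Relative to the IgG precipitates of the first experiment it was enriched in WT and K571R, at log2 3.06 and 1.86 with the IgG values as deposited and 1.97 and 0.72 after a constant factor in them was divided out.

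The RNA-seq comparison asked how mRNA levels differed between K571R and WT cells. Amino acid and stress response mRNAs were lower in K571R cells, among them TRIB3, a pseudokinase induced by ATF4, at 46.0 against 133 FPKM (log2 −1.51, counting SE 0.06) and CEBPB, a bZIP transcription factor, at 19.2 against 49.8 FPKM (log2 −1.33, SE 0.10). HES1, a transcriptional repressor downstream of Notch, was higher at 80.3 against 18.8 FPKM (log2 2.04, SE 0.11), as was the inducible chaperone HSPA1A (log2 1.34, SE 0.16), whose reads cannot be told from those of its near-identical copy HSPA1B. Of 12017 genes tested, 157 were at least 2-fold higher and 114 at least 2-fold lower in K571R cells. Simulated libraries with no effect gave 69 and 42. The RIP inputs of the same lines gave 568 higher and 461 lower among 12103 genes. A pseudocount of 0.1 in place of 1 gave 313 and 232 genes, and a minimum mean of 5 FPKM gave 53 and 48. When counts scaled to library size (CPM) replaced FPKM, 104 of the 271 genes stayed at least 2-fold apart in the same direction.

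Genes named by the fixed rule differed in the same direction by at least 0.58 on the log2 scale in the RIP inputs. The lowest in K571R were UPP1, a uridine phosphorylase (log2 −1.54 in RNA-seq and −1.80 in the inputs), AKNA, a microtubule organiser (−1.51 and −1.07), TRIB3 (−1.51 and −1.75), SERPINB8, a serpin (−1.41 and −0.84), the neutrophil chemokine CXCL2 (−1.38 and −0.85), CEBPB (−1.33 and −1.31), the small GTPase RAB39B (−1.22 and −1.51), the zinc finger gene ZNF239 (−1.21 and −0.76) and the stress-induced cytokine GDF15 (−1.17 and −1.14). RP11-508N12.4 (−1.44 and −3.57) had a counting SE of 0.96. The highest were HES1 (2.04 and 2.31), BRICD5 (1.87 and 2.25), LGR4, a receptor for R-spondins (1.42 and 0.59), the nuclear protein CSRNP1 (1.38 and 1.27), HSPA1A (1.34 and 1.38), the hypoxia- and stress-responsive repressor BHLHE40 (1.20 and 0.85) and SRRT, an RNA-processing factor (1.19 and 1.01). From CPM, BRICD5 (0.98), LGR4 (0.83), SRRT (0.61), ZNF239 (−0.83) and RP11-508N12.4 (−0.61) stayed below 2-fold, as did EIF4ENIF1 (1.82 from FPKM and 0.13 from CPM), MRPS18C (1.59 and 0.33) and PUS7 (1.19 and 0.30). In hg19 the files place UPP1 at chromosome 7, 48128224 to 48148330, TRIB3 at chromosome 20, 361260 to 378203, CEBPB at chromosome 20, 48801139 to 48809212, and HES1 at chromosome 3, 193853933 to 193856521.

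Of 31 gene lists fixed in advance, 9 had an RNA-seq median outside the middle 95% of 10000 random lists matched on mean expression. Lists of genes drawn at random would give 1.55. Members of a list can move together, so this number does not measure the spread between cultures. The 24 genes of the integrated stress response and unfolded protein response had a median log2 difference of −0.51 at percentile 0, with 20 below 0 and 4 at least 2-fold lower: TRIB3, CEBPB, the asparagine synthetase ASNS (625 FPKM in WT and 280 in K571R, log2 −1.15) and SESN2, a leucine-responsive inhibitor of mTORC1 (log2 −1.13). The same list was lower in the RIP inputs, at a median of −0.69 and percentile 0, where the amino acid transporter subunits SLC3A2 (−1.91) and SLC7A5 (−1.22) were among its lowest members. Replication-dependent histones were lower too, at −0.29 in RNA-seq and −0.31 in the inputs, both at percentile 0, with 45 of 59 genes below 0 in each. Among the largest RNA-seq differences HIST1H4K was lower (−1.65), and HIST1H2BB (2.11, SE 2.12), HIST1H2BE (1.93, SE 1.47) and HIST2H3C (1.00) were higher. In the inputs HIST2H2AA3 (4.06), HIST1H4K (3.03) and HIST2H3PS2 (2.40, SE 2.09) were higher and HIST1H4A (−1.88) lower. Histone genes share near-identical sequences.

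DNA replication genes were higher in K571R cells, with a median of 0.51 at percentile 100 and 23 of 24 above 0, including the origin-licensing factor CDC6 (1.12, or 0.99 from CPM), the flap endonuclease FEN1 (0.78), the ribonucleotide reductase subunit RRM2 (0.76) and the transcription factor E2F1 (0.70). Cholesterol biosynthesis genes had a median of 0.47 at percentile 100, with 18 of 19 above 0, including HMGCS1 (1.17, or 0.83 from CPM), IDI1 (0.78) and the SREBP pathway regulator INSIG1 (0.69). Heat shock genes (0.46, percentile 100) included HSPA1A, HSPA1B (0.77), the co-chaperones DNAJA1 (0.77) and STIP1 (0.76). Hypoxia genes (0.36, percentile 100) were led by the peptide hormone precursor ADM (1.16), PFKFB4 (1.13, or 0.93 from CPM), the demethylase KDM3A (0.78) and PDK1 (0.70). Glycolysis genes (0.27, percentile 100) were led by HK1 (0.68), SLC16A3 (0.65), ENO2 (0.61) and LDHA (0.53). Mitotic genes were slightly higher (0.20, percentile 100), with BUB1B at 0.94, KIF20A at 0.80, DLGAP5 and MKI67 at 0.54. In the RIP inputs these 6 lists also lay above the middle 95%, at medians of 0.44 for DNA replication, 0.49 for cholesterol biosynthesis and for heat shock, 0.42 for hypoxia, 0.27 for glycolysis and 0.35 for mitosis. SLC16A3 (−0.52) and CENPE (−0.71) went the other way. Targets of TGF-beta, WNT and Hippo signalling had a median of −0.18 at percentile 1.05 in RNA-seq, with ANKRD1 at −0.96 and LEF1 at −0.78 but the BMP target ID2 at 0.84 and SMAD7 at 0.56, and lay inside the middle 95% in the inputs (−0.16, percentile 6.25), with a minimum mean of 5 FPKM (percentile 10.5) and from CPM (percentile 6.41).

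**Figure D1:**
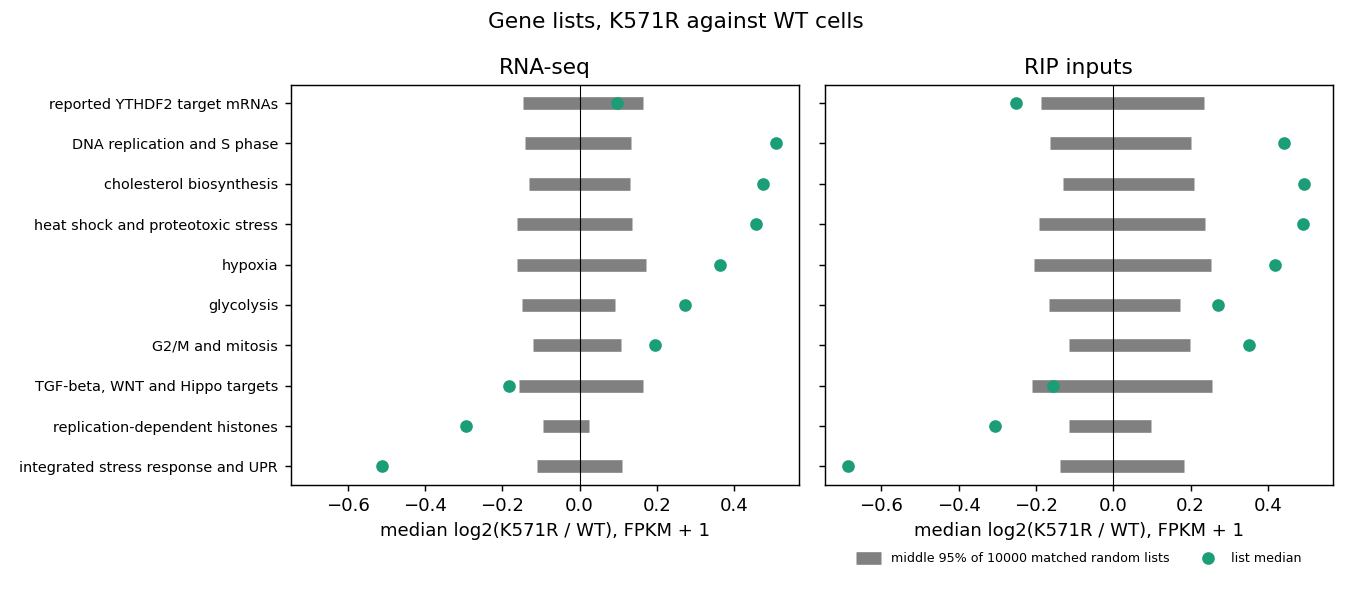
Median log2 difference between K571R and WT cells (x axis, FPKM plus 1) of 10 gene lists in RNA-seq (left) and in the RIP inputs (right); points are list medians and grey bars the middle 95% of 10000 matched random lists. The integrated stress response list lies lowest in both panels, at −0.51 and −0.69, and the reported YTHDF2 targets lie inside the bar in RNA-seq (0.10) and below it in the inputs (−0.25).

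The other lists lay inside the middle 95% in RNA-seq. The 20 measured mRNAs reported elsewhere as YTHDF2 targets had a median of 0.10 at percentile 86.1, with the transcription factor MYC at −0.49, the acetyltransferase CREBBP at 0.82, the cytokine IL11 at 1.29 against 3.60 FPKM and the splicing factor SON at 0.29. In the RIP inputs their median was −0.25 at percentile 0.69, with HIVEP2 at 0.73, the cytokine signalling suppressor SOCS2 at −0.68 and the phosphatase LHPP at −0.59. Other medians in RNA-seq were −0.01 for m6A writers, 0.06 for m6A erasers and readers, −0.01 for CCR4-NOT deadenylation factors, 0.01 for decapping and decay factors, 0.04 for the SUMO pathway, 0.02 for immediate early genes, and −0.12 for NRF2 targets. Interferon response genes stood at −0.01, NF-kB and inflammatory cytokines at −0.003, epithelial-mesenchymal and invasion genes at −0.14, receptor tyrosine kinase and MAPK signalling at −0.09, apoptosis regulators at 0.05, autophagy at −0.14 and neuroendocrine markers at 0.17. Mitochondrially encoded mRNAs had a median of −0.10, cytosolic ribosomal protein mRNAs −0.06, zinc finger (ZNF) mRNAs −0.02 and solute carriers −0.01. Of the markers of other cell types, 3 blood and immune genes (percentile 15.9) and 3 fibroblast and endothelial genes (percentile 42.7) were expressed.

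Across 12088 genes, the RNA-seq and RIP input differences between K571R and WT cells correlated with a Pearson r of 0.16, which was 0.21 among genes with a mean of at least 5 FPKM and 0.31 at 20 FPKM; genes are not independent replicates. In both, 35 genes were at least 2-fold higher, against 6.58 for independent lists, and 28 were lower, against 4.14. In opposite directions 36 genes were at least 2-fold apart, against 10.5, so overlap exceeded that of independent lists whatever the direction. Of the 63 genes that went the same way, 24 had a mean of at least 5 FPKM, as did 6 of the 36.

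The RIP pairs were compared with their inputs to see which mRNAs the Flag-YTHDF2 precipitates held. In the control pair of the second experiment the 21 measured mRNAs reported as YTHDF2 targets had a median of 0.32, inside the middle 95% of matched random lists (percentile 88.2), with 9 at least 2-fold higher than in the input and 5 lower. High were HIVEP2, a zinc finger transcription factor (log2 3.71), CREBBP (3.29), SON (3.24), CEBPA (2.94), the WNT scaffold AXIN1 (2.44), MYC (1.89), SOCS2 (1.43) and the receptor EGFR (1.34). Low were cyclin CCNA2 (−2.69), the pentose phosphate enzyme PGD (−1.90), UBXN1 (−1.88) and CDK2 (−1.27). In the WT pair of the first experiment 20 measured targets had a median of −0.21 (percentile 49.9), 0 at least 2-fold higher and 5 lower. HIVEP2 stood at 0.30, CREBBP at 0.28, SON at 0.34, AXIN1 at 0.55, MYC at −0.09 and EGFR at 0.17. At least 2-fold enrichment over input was found for 380 of 11930 genes in WT (3.19%) and 619 of 11958 in K571R (5.18%), but for 3089 of 11680 in control (26.4%), 3467 of 11543 under ginkgolic acid (30.0%) and 3163 of 11791 under 2-D08 (26.8%). Centring on all tested genes raised the WT and K571R counts to 664 and 1092. Against the IgG precipitates as deposited, 4520 genes in WT and 4530 in K571R were at least 2-fold enriched, but the IgG values carried a constant factor of 0.45 of unstated origin, and dividing by it left 853 and 1025.

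**Figure D2:**
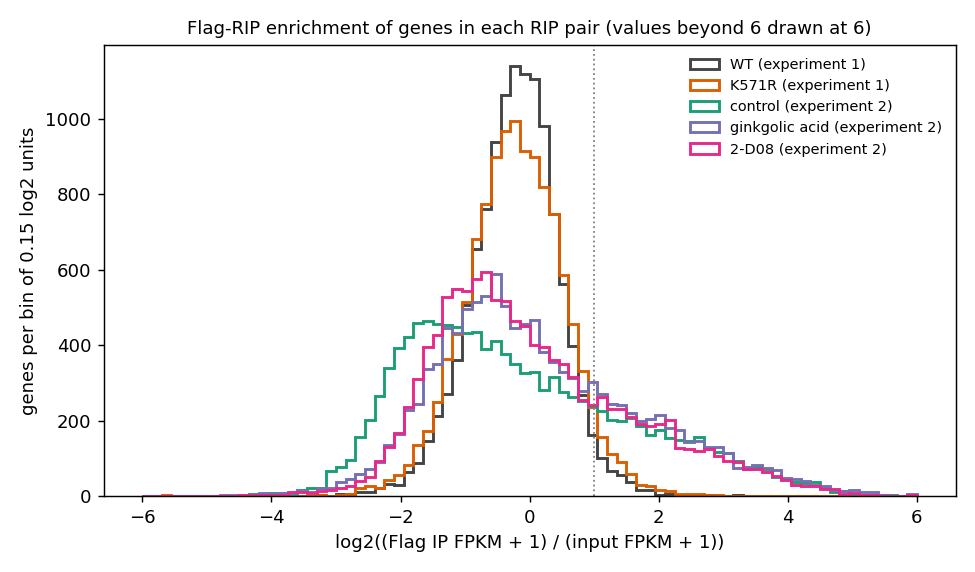
Distribution over genes of log2 Flag precipitate over input (FPKM plus 1) in each of the 5 RIP pairs, with values beyond 6 drawn at 6. The spread is narrow in the first experiment (SD 0.70 in WT and 0.80 in K571R) and wide in the second (SD 1.78 in control, 1.66 under ginkgolic acid and 1.57 under 2-D08).

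Enrichment differed more between the experiments than between conditions within them. Across 11987 genes it correlated at r = 0.62 between WT and K571R in the first experiment, at 0.82 between control and ginkgolic acid and at 0.84 between control and 2-D08 in the second, but at 0.13 between the untreated WT pairs of the experiments. Of 367 genes enriched in WT and 3004 in control, 87 were enriched in both, where independent lists give 92.0. Between these untreated WT pairs 3721 genes differed by at least 2-fold in one direction and 3434 in the other, more than in any contrast between conditions within an experiment.

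**Figure D3:**
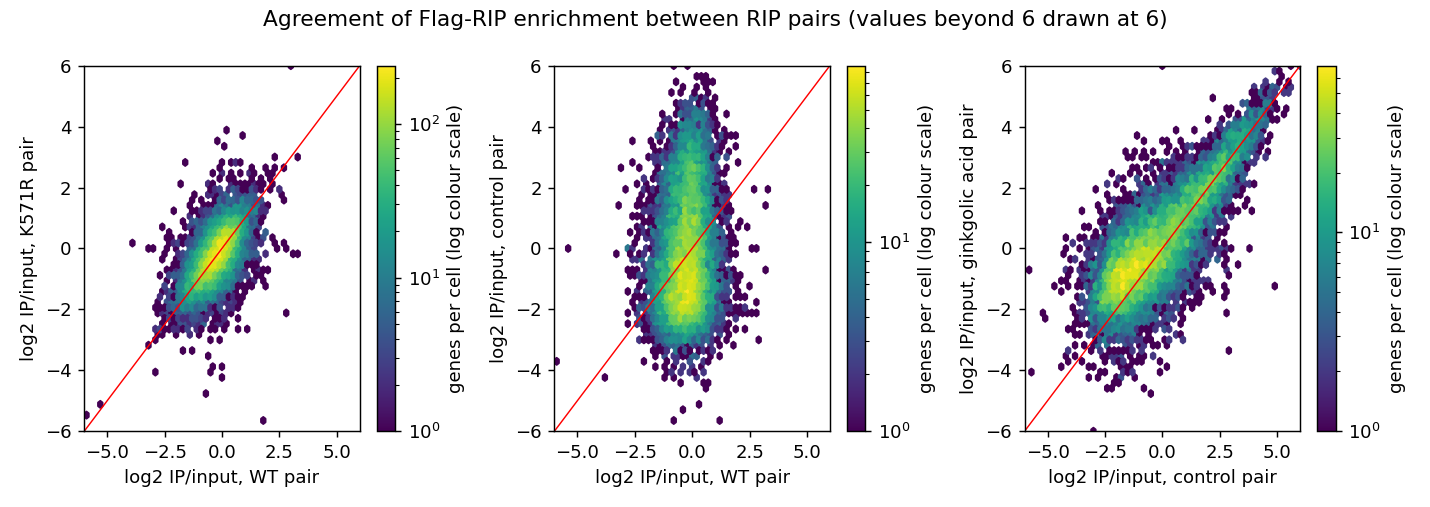
Log2 Flag precipitate over input per gene in pairs of RIP pairs, with values beyond 6 drawn at 6. The pairs within an experiment follow each other (r of 0.62 for WT with K571R and 0.82 for control with ginkgolic acid), and the untreated WT pairs of the different experiments do not (r of 0.13).

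K571R was compared with WT to ask whether the substitution altered mRNA binding. Stress response mRNAs had higher Flag enrichment in K571R, including SLC3A2 (log2 difference 1.69, counting SE 0.08), TRIB3 (1.03, or 0.99 from CPM), CEBPB (0.95) and the proapoptotic factor DDIT3 (0.90), and mitochondrially encoded mRNAs had lower enrichment, with MT-ND6 at −1.79, MT-ND5 at −1.17 and MT-ND1 at −1.11. Simulated libraries with no effect gave 266 genes at least 2-fold higher in K571R and 356 lower. Of 11994 genes measured, 622 were at least 2-fold higher and 690 at least 2-fold lower in K571R, with a median of 0.00. From CPM, 575 of these 1312 genes stayed at least 2-fold apart in the same direction. With a minimum mean of 5 FPKM these were 327 and 367, and with the second experiment's control pair as the untreated reference 3828 and 3568. The inputs differed more between the lines than the precipitates did (SD 0.58 and 0.41 on the log2 scale). Enrichment differences correlated at −0.80 with those of the inputs, which they contain with a minus sign; if precipitate and input differences were independent, that alone would give −0.82. Against the RNA-seq differences the correlation was −0.05.

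The 2829 genes bound in the separate control pair had a median K571R minus WT enrichment of −0.07, with 148 at least 2-fold higher and 192 lower. This median lay at percentile 0 of matched random sets (middle 95% from −0.03 to 0.01). Of 3004 genes enriched in control, 87 were enriched in WT as well, where independent lists give 92.0. The median therefore cannot be read as a loss of binding. Of 30 lists, 9 lay outside the middle 95%, where lists of genes drawn at random give 1.5, which leaves out the spread between cultures. Higher in K571R were the integrated stress response (0.46, with 22 of 24 above 0), replication-dependent histones (0.42, with 50 of 59 above 0, 5 at least 2-fold higher and 3 lower, HIST1H4A at 2.22 but HIST2H2AA3 at −4.01, HIST1H2BE at −1.34 and HIST2H3PS2 at −1.27), autophagy genes (0.32, with the lysosomal protein LAMP1 at 0.41, MAP1LC3B at 0.45, WIPI1 at −0.63 and TFEB at 0.48) and solute carriers (0.21, with 23 higher and 6 lower of 205; SLC25A21 at 3.05, SLC9A8 at 2.34 and SLC2A14 at 1.81 but SLC6A13 at −3.43). Lower were mitochondrially encoded mRNAs (−0.83), heat shock genes (−0.30, with HSPA1A at −1.08, DNAJB1 at −0.97, HSPA1B at −0.76 and HSPE1 at −0.69), m6A erasers and readers (−0.28, with FMR1 at −1.01 (−0.27 from CPM), HNRNPA2B1 at −0.62, IGF2BP3 at −0.58 and IGF2BP2 at 0.55), mitotic genes (−0.22, with NUSAP1 at −0.71, AURKA at −0.69, KIF20A at −0.60 and CENPE at 0.83) and ZNF genes (−0.13, with ZNF600 at −2.32, ZNF611 at −2.30 and ZNF730 at −2.20, but ZNF862 at 2.72, or 0.02 from CPM). For the stress response list the Flag precipitates themselves differed by a median of −0.19 and the inputs by −0.69. For mitochondrial mRNAs the precipitates differed by −0.75 and the inputs by 0.30. In the same order, heat shock genes stood at 0.23 and 0.49, mitotic genes at 0.10 and 0.35, and m6A erasers and readers at 0.03 and 0.23. The K571R precipitates thus did not hold less of these mRNAs by median, and their inputs held more. Autophagy genes stood at −0.03 and −0.18, histones at 0.11 and −0.31, solute carriers at 0.11 and −0.07, and ZNF genes at −0.11 and 0.02. Taking the second experiment's control pair as the reference adds the difference between the experiments, which cannot then be told apart from that of the lines. With that reference, the heat shock and mitotic lists changed sign, to 0.10 and 0.54 relative to matched random lists. The integrated stress response (percentile 96.5), autophagy (80.4), solute carrier (78.1) and m6A eraser and reader lists (35.4) fell inside the middle 95%. Solute carriers also fell inside it without the filter on low values (percentile 50), and autophagy (95.3) and mitotic genes (4.52) did so from CPM.

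Reported YTHDF2 targets had a median K571R minus WT enrichment of 0.15 at percentile 88.5, with none of 20 beyond 2-fold. SON stood at −0.81, HIVEP2 at −0.60, SERPINE2 at −0.52, CREBBP at 0.44, MYC at 0.20, EGFR at 0.16, AXIN1 at 0.06, LHPP at 0.77, CDK2 at 0.84, NR1H3 at 0.92, UBXN1 at 0.41, ATG7 at 0.32, ATG5 at 0.14, PGD at 0.05, CCNA2 at −0.01, SOCS2 at −0.07, KDM6B at −0.10 and IL11 at −0.27. Among genes taken by the rule, the lowest were SMN1 (−7.48, SE 0.71), whose reads are split with the near-identical SMN2, C6orf52 (−2.94, SE 1.13), C2CD2 (−2.79) and the actin-binding CALD1 (−2.53). From CPM, C2CD2 came to −0.80, CALD1 to −0.43 and TPRN (−3.05) to 0.10. The highest with a value above 0 in every library were DCAF17 (2.75), CCDC41 (2.51, or 0.72 from CPM), the glypican GPC2 (2.47), CNEP1R1 (2.45) and AAMDC (2.43). The remaining genes taken by the rule were listed at 0 in 1 or more of the libraries: AP000758.1, AC007382.1, SLC6A13, IFRG15 and FAM27E3 on the lower side and the read-through locus HSPE1-MOB4, FAM206A, RP11-500M8.7, PRR24 and COMTD1 on the higher side.

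Ginkgolic acid was compared with control cells to ask whether blocking SUMO activation altered binding. Histone, heat shock and mitotic mRNAs had higher Flag enrichment under the drug than other genes of like expression. Among reported targets, HIVEP2 stood at 0.07, SON at 0.01, MYC at −0.04, AXIN1 at −0.10, EGFR at 0.19 and CREBBP at −0.20. Of 11674 genes, 2796 were at least 2-fold higher and 971 at least 2-fold lower, 25.8% of them lower, but all genes together had a median of 0.34, and after centring the split was 1699 and 1633, or 49.0% lower. Simulated libraries with no effect gave 1054 and 456, an uneven split that may hold more than counting noise. From CPM, 2159 of the 3767 genes stayed at least 2-fold apart in the same direction. The 325 genes bound in the separate WT pair had a median of 0.55 at percentile 99.9 of matched sets (middle 95% from 0.25 to 0.50), and this place was lost with a pseudocount of 0.1 (percentile 94.0) or without the filter on low values (percentile 96.6). Of 367 genes enriched in the WT Flag precipitate, 119 (32.4%) were also enriched at least 2-fold in the K571R IgG precipitate over the K571R input. Independent lists give 49.8, the IgG values were divided by their factor, and these libraries are not shared with the WT pair. Of the same 367 genes, 87 were enriched in control, where independent lists give 92.0. The median of the bound genes therefore cannot be read as a gain of binding.

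Of 29 lists, 6 lay outside the middle 95% under ginkgolic acid, and 5 of them are described here. Replication-dependent histones had a median of 1.30, where matched random lists gave 0.56, with 39 of 57 at least 2-fold higher, among them HIST2H2AA3 (5.03), HIST1H2BL (3.40), HIST2H4B (3.33) and HIST1H4K (3.21). The 4 expressed neuroendocrine markers had a median of 1.78 against 0.37 for random lists, the granin SCG2 at 2.38, the Notch ligand DLL3 at 2.12, UCHL1 at 1.44 and, below 2-fold, ENO2 at 0.76; the list fell inside the middle 95% without the filter on low values (percentile 46.2, with 13 members) and with a minimum mean of 5 FPKM (percentile 97.1, with 3 members). Heat shock genes (0.98 against 0.47) included the co-chaperone STIP1 (1.70), HSPH1 (1.55), HSPE1 (1.44) and CHORDC1 (1.31), the last 3 at 0.41, 0.83 and 0.88 from CPM, but the list fell inside the middle 95% with a pseudocount of 0.1 (percentile 97.47) and without the filter (percentile 92.7). Mitotic genes (0.86 against 0.44) included the kinase TTK (2.19), CCNB2 (1.64), NUSAP1 (1.54) and KIF23 (2.83-fold). ZNF genes stood below other genes, at 0.13 as measured against 0.35 for random lists and −0.21 after centring, with ZNF583 at −2.55, but ZNF835 (2.85), ZNF547 (2.80) and ZNF540 (2.51, or 0.96 from CPM) went the other way. For histones the precipitates differed by 0.31, inside the middle 95% (percentile 36.7), and the inputs by −0.93 (percentile 0); for mitotic genes these were 0.57 (percentile 96.8) and −0.38 (percentile 2), and for heat shock genes 0.53 (percentile 86.8) and −0.32 (percentile 14.9). All tested genes differed by 0.13 and −0.20. With the first experiment's WT pair as the reference, the heat shock, mitotic and ZNF lists changed sign, to −0.28, −0.56 and 2.19 relative to matched random lists. The histones (percentile 93.9) and neuroendocrine markers (61.4) then fell inside the middle 95%. That reference adds the difference between the experiments, from which these changes cannot be told apart. Reported targets had a median of 0.06 (−0.29 after centring) at percentile 5.24, with CCNA2 (1.23), UBXN1 (1.21), PGD (1.06) and SERPINE2 (1.02) higher and SOCS2 (−1.06) lower. From CPM, UBXN1 came to −0.04, PGD to 0.70 and SERPINE2 to 0.94. CEBPA (0.04, SE 2.12), ATG5 (0.71), KDM6B (0.60), NR1H3 (−0.49), LHPP (−0.99), ATG7 (−0.57) and CDK2 (−0.13) did not reach 2-fold.

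Genes taken by the rule as lowest under ginkgolic acid included the DNA-protein crosslink protease SPRTN (−3.99, SE 0.59), the lipase activator ABHD5 (−3.83, SE 1.47) and C15orf61 (−3.54, SE 1.47). FOPNL, ACYP2, BOLA2B, the SUMO ligase NSMCE2, PIGB and GNG10 were listed at 0 in the ginkgolic acid precipitate, and RCC1 close to 0. The highest were the synaptotagmin SYT5 (4.93, SE 0.35), the glutathione transferase MGST1 (4.71, SE 1.21), KLHL7 (4.21), the ubiquitin-like ISG15 (16.0-fold), the replication factor GINS4 (3.88), the helicase DDX1 (3.88) and the splicing-related SART3 (3.69). ZC3H8 (3.97) came to −0.14 from CPM. RP11-500M8.7 was listed at 0 in the control precipitate and the phosphatase ILKAP close to 0.

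2-D08 was compared with the same control cells to ask whether blocking SUMO transfer altered binding. Cholesterol synthesis, ribosomal protein and histone mRNAs had higher Flag enrichment than other genes of like expression, including MSMO1 (1.62), RPL22 (1.86) and HIST2H2AA3 (4.62). Of 11782 genes, 2238 were at least 2-fold higher and 1030 at least 2-fold lower, 31.5% of them lower. Simulated libraries with no effect gave 701 and 570. All genes had a median of 0.22, and centring gave 1580 and 1518, or 49.0% lower. From CPM, 2034 of the 3268 genes stayed at least 2-fold apart in the same direction. The 325 genes bound in the separate WT pair had a median of 0.30 at percentile 78.2 of matched sets (middle 95% from 0.13 to 0.38). Matched on effective length as well, this set stood at percentile 32.8. The 20 bound at a log2 of at least 2 stood at percentile 97.8, above the middle 95%. Genes enriched in WT and in control overlapped in 87, where independent lists give 92.0. None of these values can therefore be read as a gain of binding.

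Of 29 lists, 5 lay outside the middle 95% under 2-D08. Histones had a median of 1.06, where matched random lists gave 0.51, with HIST2H2AA4 at 5.26, HIST1H4K at 3.95 and HIST2H4B at 3.62. Cytosolic ribosomal protein mRNAs had a median of 1.03, where random lists of like expression gave 0.81 (middle 95% from 0.71 to 0.91), with 46 of 80 at least 2-fold higher and none lower, including RPS27L (1.88) and RPS29 (1.49). Cholesterol biosynthesis genes (0.83 against 0.23) included MSMO1 (1.62), INSIG1 (1.62, or 0.53 from CPM) and the decarboxylase MVD (3.48, or 0.76 from CPM), and DNA replication genes (0.66 against 0.20) the helicase component CDC45 (3.29), ORC1 (1.99), MCM5 (1.94) and MCM2 (1.76). The DNA replication list fell inside the middle 95% with a pseudocount of 0.1 (percentile 97.38), when matched on length (97.37) and from CPM (95.9), and the cholesterol list from CPM (96.9). ZNF genes had a median of −0.05 against 0.21 for random lists, although ZNF789 (3.16), ZNF628 (2.90), ZNF547 (2.15) and ZNF143 (2.09) stood high. In the precipitates themselves cholesterol genes differed by 1.02 and ribosomal protein genes by 0.82, and in the inputs by 0.13 and −0.18. DNA replication genes differed by 0.29 in the precipitates, inside the middle 95% (percentile 63.8), and by −0.27 in the inputs, below it (percentile 0.02), and histones by 0.65 (percentile 98.9) and −0.45 (percentile 0). With the first experiment's WT pair as the reference, the DNA replication, ribosomal protein and ZNF lists changed sign, to −0.66, −0.38 and 2.12 relative to matched random lists. The histones (percentile 89.3) and cholesterol genes (61.8) then fell inside the middle 95%. These changes cannot be told apart from the difference between the experiments, which that reference adds. Reported targets had a median of −0.08 at percentile 8.31, with UBXN1 (1.09) at least 2-fold higher, CREBBP at −0.82, HIVEP2 at −0.66, AXIN1 at −0.65, SON at −0.50, EGFR at −0.18 and MYC at −0.08.

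By the rule, the lowest under 2-D08 were C21orf119 (−7.53, SE 2.55), the signal peptidase subunit SPCS2 (−3.54), the membrane skeleton protein EPB41 (−3.52) and TMA16 (−3.31, SE 1.05). The proapoptotic BID (−3.10) and the kinase DCK (−3.05) came to −0.43 and −0.48 from CPM. The read-through locus COMMD3-BMI1, ACYP1, ST20 and PRRT1 were listed at 0 in the 2-D08 precipitate. The highest were HIST2H2AA4, the mitochondrial protease OMA1 (3.96), HIST2H4B, AKR1E2 (3.56, SE 1.84), MVD, the ethanolamine kinase ETNK1 (3.34), ZC3H15 (3.29), CDC45 and ZNF789, while the lipase MGLL (4.76) came to −0.73 from CPM.

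Differences under ginkgolic acid and under 2-D08 correlated across 11987 genes at r = 0.47 with a covariance of 0.47. These comparisons share the control pair. Simulated libraries with no effect gave r = 0.48 with a covariance of 0.25 from simulated counts. With the spread between the experiments, which may be more than noise, they gave r = 0.51 with a covariance of 1.63. The shared control alone thus gives as large a correlation. The measured covariance lay between the simulated ones. No replicate gives the spread within an experiment, so the covariance cannot decide whether the response was shared. At least 2-fold higher under both were 1139 genes and lower under both 337, numbers that the shared control raises by itself. With the WT pair of the first experiment as the reference of 1 of the 2 comparisons, the correlation was −0.17 or −0.21. That comparison then holds the difference between the experiments, so these values do not measure a shared response. Set directly against each other, ginkgolic acid was at least 2-fold higher than 2-D08 for 1871 genes and lower for 1396. The drugs were given for different times, 12 h and 24 h. K571R minus WT differences correlated with those of ginkgolic acid and of 2-D08 at 0.03 each.

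The MeRIP peak lists were compared to ask how m6A marks differed between WT and K571R cells. Strong peaks were found in both lines in HSPBAP1 (hg19 chromosome 3, 122459438 to 122459722, authors' fold enrichment 2052 in WT), in the fucosyltransferase FUT8 (chromosome 14, 66208872 to 66210081, fold 1927 in WT and 2114 in K571R) and in CCDC136 (chromosome 7, 128450193 to 128450420, fold 1153 in WT and 3438 in K571R). Shared peaks in reported targets lay in MYC (chromosome 8, 128752642 to 128753514 in WT, fold 9.01, against 6.84 in K571R), SON (chromosome 21, 34921782 to 34922791, fold 56.1 against 22.0), HIVEP2 (chromosome 6, 143082601 to 143082702, fold 149 against 34.1), CREBBP (chromosome 16, 3778385 to 3779264, fold 25.3 against 47.9) and SERPINE2 (chromosome 2, 224849469 to 224849499, fold 42.6 against 22.8). The authors' lists held 8652 peaks in 5457 genes for WT and 8897 peaks in 5667 genes for K571R. At 1 shared base or more, 2056 WT peaks (23.8%) and 2043 K571R peaks (23.0%) overlapped, and 3260 genes had a peak in both lists. Among expressed genes 3130 were marked in both, where independent lists give 2200. Shared peaks had median folds of 20.1 in WT and 20.9 in K571R, and peaks of 1 list 14.6 and 15.1. Across 2040 pairs that overlapped 1 to 1, the log2 fold of K571R over WT had a median of 0.04 and an SD of 1.42.

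Among peaks found in 1 list, the highest folds were in CGRRF1 (1386), the tight junction gene CGN (1014), ZNF839 (1001), the kinesin KIF5B (950) and LRRCC1 (945) in WT, and in the exocyst gene EXOC6 (2520), FAM184A (1232), ZDHHC23 (1194), the collagen COL1A1 (1149) and DOCK1 (1138) in K571R. Other shared peaks with high folds lay in ZFP1 (1240 in WT), the TMEM56-RWDD3 read-through locus (1198 in WT) and CCDC8 (1540 in K571R). AXIN1, ATG5, CDK2 and NR1H3 had peaks in WT cells and SOCS2, EGFR and TNFRSF1B in K571R cells, at highest folds of 79.8, 6.95, 13.0, 54.5, 53.2, 6.62 and 44.3 in that order. The authors' false discovery rates had a median of 14.6% in WT and 21.1% in K571R, and 1 WT peak and 0 K571R peaks lay at or under 5%, so a peak found in 1 list is weak evidence that the lines differ there. No annotation of hg19 was used here, and exons and untranslated regions at the peaks are not given.

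Flag enrichment of m6A-marked genes was compared with that of unmarked genes because YTHDF2 reads m6A. Among expressed genes, marked genes had the higher median in every pair, by a difference of medians of 0.09 in WT, 0.05 in K571R, 0.58 in control, 0.45 under ginkgolic acid and 0.37 under 2-D08, at percentiles of 99.9 or above among sets matched on expression. When sets were matched on effective length as well, WT and K571R kept percentiles of 100 and 99.9, whereas control (75.9), ginkgolic acid (39.5) and 2-D08 (73.8) did not stand out. From CPM, K571R fell inside the middle 95% of sets matched on expression (percentile 88.7). Without the filter on low values the difference of medians was −0.15 in WT, −0.19 in K571R, −0.09 in control, 0.12 under ginkgolic acid and 0 under 2-D08, with percentiles from 99.8 to 100 among sets matched on expression. At least 2-fold enriched were 2.77% of marked and 3.50% of unmarked genes in WT, 4.14% and 5.94% in K571R, 31.5% and 22.6% in control, 34.7% and 26.4% under ginkgolic acid, and 30.4% and 24.1% under 2-D08. Enrichment was higher for genes of greater effective length in the second experiment, at a Spearman rho of 0.43 in control, 0.37 under ginkgolic acid and 0.34 under 2-D08, but not in WT (0.03) or K571R (−0.02).

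**Figure D4:**
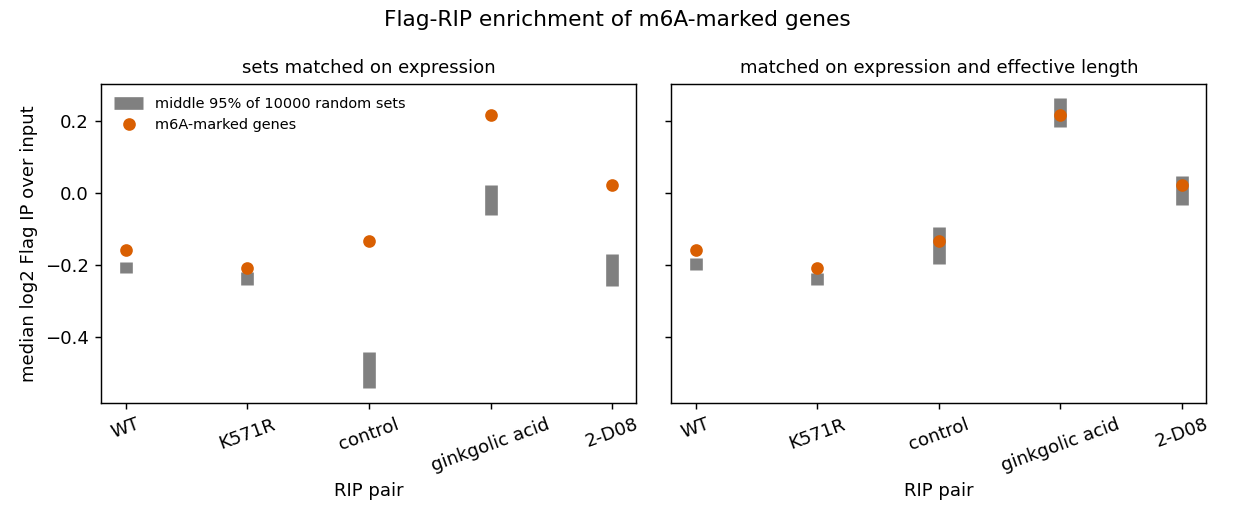
Median log2 Flag precipitate over input of m6A-marked genes (points) in the 5 RIP pairs beside the middle 95% of 10000 random sets (grey bars) matched on expression (left) or on expression and effective length (right). In the second experiment the points lie above the bars on the left, at percentile 100, and inside them on the right, at percentiles from 39.5 to 75.9.

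Levels of mRNAs that were both bound and marked were then compared between K571R and WT cells, since YTHDF2 directs such mRNAs to decay. The 1561 genes bound in the control pair and marked in WT, a set that holds HIVEP2, CREBBP, SON, AXIN1 and MYC, had a median RNA-seq difference of 0.05 at percentile 100 (middle 95% of matched sets from −0.01 to 0.02), with 14 at least 2-fold higher and 3 lower. Genes bound without a mark had a median of 0.03 (percentile 94.8) and marked genes that were not bound 0.01 (percentile 93.4). The 140 marked genes bound in the WT pair of the first experiment did not stand apart in RNA-seq, at −0.02 and percentile 27.6. In the RIP inputs they stood at 0.22 and percentile 100, but the WT input also served to choose them. In the RIP inputs the genes bound in the control pair and marked had a median of 0.04 at percentile 91.4, and those bound without a mark 0.05 at percentile 98.8. Matching on effective length put the RNA-seq value of the bound and marked genes at percentile 95.7, inside the middle 95%.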

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

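Tests chosen only after the result was seen were the rank correlation, the place of the stress response list in the RIP inputs, its differences over counting error and the YTHDF2 level; the other tests were set down before.

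In 36 genes K571R and WT cells differed by at least 2-fold in opposite directions in RNA-seq and in the RIP inputs, against 10.5 for independent lists, and the difference itself was not tested. These genes were low, with a median of 2.69 FPKM against 15.0 for all genes, and 6 of them had a mean of at least 5 FPKM. The IgG precipitates, left out of the main comparisons, held RNA of their own: after division by the factor, 997 genes in WT and 1735 in K571R were at least 2-fold higher than in the input.

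The untreated WT pairs of the RIP experiments hardly followed each other in Flag enrichment. Low depth is argued against, since r was 0.0774 among 4449 genes with a mean input of at least 20 FPKM. The rank correlation, which no scaling changes, was 0.13. A constant scaling hardly alters r of log ratios either, so this value adds little. Background RNA in the first experiment's Flag precipitates stays open: WT Flag enrichment correlated at 0.23 with the enrichment of the K571R IgG precipitate, which shares no library with it, below the 0.5 set for this explanation and above the bound of 0.2 that would have excluded it. Of 367 genes enriched in WT Flag, 119 were also at least 2-fold above input in that IgG precipitate, against 49.8 for independent lists. The spread of Flag over IgG was 0.82, against 1.75 for the second experiment's Flag over input. A difference between the experiments in precipitation or cells was not tested, since no condition was run in both besides untreated WT.

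Integrated stress response mRNAs were lower in K571R than in WT cells. Noise of 1 library pair is argued against by the RIP inputs, where the list lay at percentile 0; counting error by a median difference of −8.94 counting errors over the 24 genes; and effective length bias by percentile 0 among sets matched on length. The YTHDF2 level or state of the stable lines cannot be told apart from the substitution, because the series holds 1 line of each kind and YTHDF2 mRNA differed by 0.57 on the log2 scale. K571R may lower these mRNAs, as a hypothesis, but a difference between stable lines may do so as well.

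Enrichment in the second experiment's Flag precipitates went with transcript length, at a Spearman rho of 0.34 or more and up to 0.43 in its 3 pairs. Among sets matched on expression and effective length, m6A-marked genes stood at percentiles from 39.5 to 75.9, so they did not stand out. This cannot exclude m6A marking as a source of their higher enrichment. Matching on length also takes out any m6A sites that come with length, and the matched sets held marked genes as well. The marks are uncertain too, since 1 WT peak lay at or under a false discovery rate of 5%. Longer mRNAs may be enriched because of more binding sites or because of fragment recovery, which these files do not separate. No other biological explanation was tested.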

How the results depend on the processing

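Added after the data had been seen were CPM from estimated counts, IgG divided by its factor and the list alternatives (length-matched, another untreated pair, RIP inputs); the rest were set before the data were examined. Of 200 values of 31 main results under alternatives, 154 were kept, 35 moved, 6 became weaker, 1 stronger and 4 reversed. Of 1047 values of 305 single genes and lists, 875 were kept, 134 moved, 26 became weaker and 12 reversed. Kept counts changed by at most 1.5-fold, and kept sets stayed inside the middle 95% or outside it on the same side. Kept correlations stayed within their 95% interval over genes, and kept single genes within counting error. A kept set could differ in size or, inside the middle 95%, in sign. The most abundant transcript was not run, as the tables were per gene, and IgG could not serve as reference for the second experiment, whose tables used here hold none. No paired analysis was possible because each group held 1 library. Depth limits single genes: with a minimum mean of 5 FPKM fewer genes were tested and fewer were called. Except where stated, the cause was not tested. Values of sets and lists below are medians minus those of matched random sets.

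With a pseudocount of 0.1, RNA-seq gave 313 higher and 232 lower genes, genes bound in the WT pair 0.10 under ginkgolic acid (percentile 94.0), the correlation of the drugs was 0.45 and that of K571R with 2-D08 0.00574. Without the filter the ginkgolic acid value was 0.10 (percentile 96.6), and the difference of medians of marked and unmarked genes was −0.15 in WT, −0.19 in K571R, −0.0944 in control and 0 under 2-D08, at percentiles of 99.8 or above among matched sets. With a mean of at least 5, K571R minus WT gave 327 higher and 367 lower, ginkgolic acid 518 lower, 2-D08 610 lower, RNA-seq 53 higher and 48 lower, and the drugs correlated at 0.49. Centring, which by construction adds the shift of all genes, gave 664 enriched genes in WT, 1092 in K571R, and 1699 higher and 1633 lower under ginkgolic acid.

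With another untreated WT pair, K571R minus WT gave 3828 higher and 3568 lower, ginkgolic acid 2289 lower and 2-D08 3618 higher and 2454 lower. Genes bound in the WT pair stood at −1.57 under ginkgolic acid and −1.58 under 2-D08, by construction, since that pair then served as choice and reference. For the same reason genes bound in the control pair stood at −2.57 for K571R. The drugs correlated at 0.80, and K571R at −0.76 with ginkgolic acid and −0.78 with 2-D08, which by construction holds the difference of the experiments in each term. Lists that reversed were heat shock (0.10) and mitosis (0.54) for K571R and heat shock (−0.28), mitosis (−0.56) and ZNF genes (2.19) for ginkgolic acid. For 2-D08 they were DNA replication (−0.66), ribosomal proteins (−0.38) and ZNF genes (2.12). These list values hold the difference of the experiments too.

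Bound genes at a log2 of at least 2, of which 20 were left, gave 0.47 under 2-D08, at percentile 97.8. Matching on length put bound and marked genes at 0.015 in RNA-seq, and the RIP inputs put them at 0.019 and gave 568 higher and 461 lower genes. IgG as reference gave 4520 enriched genes in WT and 4530 in K571R, and divided by its factor 853 and 1025. CPM gave 0.048 for marked against unmarked genes in K571R (percentile 88.7) and a correlation of 0.045 for K571R with 2-D08; TPRN came to 0.10, UBXN1 to −0.0400, ZC3H8 to −0.14 and MGLL to −0.73. Of peaks at or above the median fold of their list, 896 of 4327 in WT (20.7%) and 894 of 4450 in K571R (20.1%) were shared. The counts fell because each list was cut, and the shares in the full lists were 23.8% and 23.0%. In each list 3260 genes had a peak, a count of genes that cannot be set against counts of peaks.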

Other observations

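The comparisons of input libraries in the second experiment were described only after the data had been seen, and the lists and the rule for their members were fixed before.

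Total mRNA levels in the inputs titled for ginkgolic acid were lower than in control for growth-related groups. Replication-dependent histones had a median log2 difference of −0.93 at percentile 0 of matched random lists, with 21 of 59 at least 2-fold lower, including HIST2H2AA3 (−2.96), HIST2H3C (−1.60) and HIST2H4B (−1.39), which share near-identical copies. DNA replication genes stood at −0.55, with the helicase subunit MCM6 at −1.17, FEN1 at −1.16, CDC45 at −1.16 and MCM7 at −1.05, and mitotic genes at −0.38, with MKI67 at −0.73, TOP2A at −0.67, CCNB1 at −0.55 and BUB1 at −0.52. Immediate early genes stood at −0.42, with JUNB at −1.78, IER2 and the phosphatase DUSP6 at −1.21 and FOS at −1.12. Integrated stress response genes were higher, at 0.30 and percentile 100, with the transporter subunit SLC7A5 at 0.98, TRIB3 at 0.88, ASNS at 0.74 and SLC7A11 at 0.67. Hypoxia genes stood at 0.16, with ANGPTL4 at 0.72, MXI1 at 0.69 and VEGFA at 0.45, mitochondrially encoded mRNAs at 0.37, with MT-CO2 at 0.88 and MT-CO1 at 0.54, NF-kB and cytokine genes at 0.10, with CXCL3 at 1.14 and RELB at 0.44 but LIF at −0.73 and NFKB1 at −0.39, and ribosomal protein mRNAs at 0.08, with RPL39 at 0.56. Solute carriers stood at −0.03 and, after centring, at 0.17, with SLC35A1 at 1.75 but SLC4A8 at −1.61 and SLC35E4 at −1.45. Of 11292 genes 75 were at least 2-fold higher and 361 lower, 82.8% of them lower, with a median of −0.20 over all genes; centring gave 153 and 147, or 49.0% lower. From CPM, 151 of the 436 stayed at least 2-fold apart.

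In the inputs titled for 2-D08, immediate early genes were lower, at a median of −0.49 and percentile 0, with the transcription factors EGR1 at 38.6 against 253 FPKM (log2 −2.68), FOS at −2.57, FOSB at −1.56 and JUNB at −1.35. NRF2 targets were higher, at 0.28 and percentile 99.9, with the heme oxygenase HMOX1 at 1.05, the glutathione synthesis subunit GCLC at 0.74, NQO1 at 0.73 and the cystine transporter SLC7A11 at 0.63. Autophagy genes stood at 0.19, with the receptor SQSTM1 at 0.72 but ULK2 at −0.73 and ULK1 at −0.49, mitochondrially encoded mRNAs at 0.63, with MT-CO1 at 0.85 and MT-ND5 at 0.82, and solute carriers at 0.19, with SLC16A5 at 1.20. Histones (−0.46, HIST2H2AA3 at −2.54 and HIST1H4K at −1.96 but HIST1H2BB at 1.83 and HIST2H3PS2 at 1.16), mitotic genes (−0.31, TOP2A at −0.67 and HMMR at −0.55), DNA replication genes (−0.27, MCM2 at −0.99 and MCM4 at −0.91) and heat shock genes (−0.32, HSPA8 and HSP90AA1 at −0.63) were lower. Of 11412 genes 161 were at least 2-fold higher and 127 lower, and 130 of the 288 stayed so from CPM. These comparisons share the control input, and each rests on 1 library per group.

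In the inputs of K571R against WT cells, 11 of 30 lists lay outside the middle 95%. Besides those described, apoptosis regulators stood at −0.26, with the death receptor TNFRSF10B at −0.70 but the apoptosome component APAF1 at 0.98 and BCL2L11 at 0.70, and mitochondrially encoded mRNAs at 0.30, with MT-ATP8 at 1.28 and MT-ND4 at 0.76 but MT-CO1 at −0.91.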
